A study of Mus musculus with 6 samples.

How the data were processed

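Polyadenylated RNA of 6 mouse embryonic stem cell samples was sequenced from NEBNext Ultra libraries, per the labels' protocols: 3 samples after 6 days of ethanol vehicle and 3 after 6 days of 4OHT. Groups and replicate numbers were taken from the labels. The deposited table holds whole-number read counts for 23999 gene symbols in the 6 samples, and the authors' processing notes name STAR, DESeq and the mm9 genome build without versions. Its library totals differ as raw counts do, so the values were taken as counts to which no size factor had been applied. The counting tool, the gene annotation and the use of strand are not given in the sources used here. The design fixed before the data were examined expected normalized values and named edgeR for the case of raw counts, and that case applied. No column of other samples was in the table. The library totals ran from 515388 counts in 4OHT replicate 2 to 55194644 in 4OHT replicate 1.

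Genes were tested with edgeR 4.0.16 in R 4.3.3. Low genes were removed with filterByExpr (minimum count 10), which left 14458, libraries were scaled with TMM factors (0.979 to 1.017), and a quasi-likelihood model with 1 term for treatment was fitted to all 6 samples. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with 0.05 as the threshold. Log2 fold changes are 4OHT over vehicle with a prior count of 0.125, their SE comes from the same model, and the intervals are at the 95% level. Levels are TMM-scaled CPM, given as mean ± SD over the 3 samples of a group. The model weighs libraries by depth and the mean CPM does not, so for low genes the fold change follows 4OHT replicates 1 and 3 more closely than the mean does. In 4OHT replicate 2 a level that rests on 3 reads is 5.73 CPM, while it lies between 0.0548 and 0.149 CPM in the other 5 libraries.

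The 24 gene lists were fixed before the data were examined and tested against all other tested genes with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and adjustment over the 24 lists. Each list was tested again with a correlation estimated from the data, and with fry, which asks whether the members of a list move on balance one way. A list member counts as higher or lower when its adjusted p over all tested genes passed, and the count adjusted over the list alone stands beside it. Camera passed 7 lists with the preset correlation and 0 with estimated correlations, where 1 list, that of the endoderm, had an unadjusted p under 0.05. Fry gave adjusted p of 0.0227 for the endoderm, 0.0292 for the two-cell-like and interferon-stimulated and 0.0426 for the germline and trophoblast lists. For the sterol and glycolysis lists, which passed camera, the fry adjusted p were 0.0514 and 0.0637. Among lists that camera did not pass, fry gave 0.0227 for p53, WNT and imprinted genes. It gave 0.0292 for neuroectoderm and histone genes, 0.034 for the formative list and 0.0426 for the cell cycle list. The genes named were chosen by a rule also fixed before the data were examined: Nanog, Pou5f1 and Sox2, the tested neighbours of Nanog, the 8 largest rises and the 8 largest falls with at least 50 normalized counts in the higher group and no overlap between groups, leaving out predicted genes, and up to 4 members of each list with the smallest adjusted p. A result for 1 gene under this rule is not reported here. Genes named outside this rule are said to have been picked after their values were seen.

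Same-numbered samples of both groups were checked for pairing. Over 3674 genes with log2 CPM above 6, the deviations from the group means correlated at 0.57, 0.15 and 0.38 across genes for replicates 1, 2 and 3. All 3 values exceed 0.1, so a pairing by number is possible, but no label says what the numbers mark. Any such pairing would be uneven, since vehicle replicate 2 correlated more with 4OHT replicate 3 (0.43) than with its own number. Replicate 1 is also the deepest library of each group. The main fit left a pairing out, as fixed before the data were examined, so its counts, p-values and intervals are unpaired. A fit with the replicate number as a block was made beside the tests of single genes and of gene lists, but not for the gene families, the gene order around Nanog or the chromosomes. No 2 libraries agreed within sampling noise: the lowest chi-square per degree of freedom was 1.13 (p = 2.83e-18), for 4OHT replicates 2 and 3, and this measure is lower at low depth, so it does not rank the pairs by similarity.

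Transcripts and gene models of GENCODE vM21 and gene order from RefSeq, both on the GRCm38 assembly, served for GC content, length, gene order, exon overlaps and near-identical copies (blastn 2.17.0, 95% identity over at least 50% of the transcript). That assembly differs from mm9, so no coordinate is given. The edgeR procedure was tested on simulated counts for the 14458 genes of 4OHT against vehicle, with 200 genes changed in each of 5 draws. It recovered 76.1% of genes changed 1.5-fold, 93.4% of those changed 2-fold and 99.1% of those changed 4-fold. Of its calls 10.1% were unchanged genes, and 4.99% of unchanged genes had an unadjusted p under 0.05. The share of 10.1% lies above the 0.05 that the adjusted p threshold aims at, so the simulated calls did not hold that rate. Only 200 genes were changed there against 3233 called in the data, so the share need not apply to that count. In a separate single draw camera (limma) gave a p of 0.507 for an unchanged list of 20 genes and a p of 2.32e-70 for a list of 20 genes raised 1.5-fold. The genes of that draw were independent of each other, so it cannot show whether the preset correlation of 0.01 holds for the real lists. Among the 7 lists that passed camera, the correlations estimated from the data ran from 0.02 for trophoblast to 0.76 for the two-cell-like list.

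The alternatives fixed before the data were examined were other prior counts (0.5 and 5), no filter on low counts or a mean count of at least 50, the replicate block, upper-quartile and DESeq2-type factors, quantile normalization with limma-voom, a quasi-dispersion without trend or with robust estimation, DESeq2 1.42.0, an added log2 fold change of at least 1, estimated correlations for the lists, and each library left out in turn. Those added after the data were seen were thinning of all libraries to the depth of the shallowest, limma-voom with sample quality weights, and DESeq2 with 4OHT replicate 2 left out.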

Results

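The data were gene-level read counts from polyadenylated RNA of mouse embryonic stem cells, the pluripotent cells of the early embryo kept in culture. By their labels the cells carried a floxed element, named -5, and an exogenous copy of mouse Nanog with a V5 tag. They were kept for 6 days with ethanol as vehicle (n = 3) or with 4-hydroxytamoxifen, written 4OHT (n = 3), the ligand often used to switch on Cre recombinases fused to an oestrogen receptor. The series title places the work on a Nanog enhancer, so the comparison of 4OHT with vehicle asked what happened to Nanog and to other genes after treatment of cells with this floxed element. The vehicle libraries held 52250671, 20030423 and 26370388 counts. The 4OHT libraries held 55194644, 515388 and 31307423 counts, so that 1 read in 4OHT replicate 2 was worth 1.91 CPM (read counts scaled to a fixed library total) and 2028 of the 14458 tested genes had no read there. The ribosomal RNA precursor Rn45s took 0.469% to 0.641% of the counts of the 6 libraries, and the 10 most abundant genes took 4.74% to 5.01%.

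Nanog, which encodes a homeobox transcription factor of pluripotent cells, fell to 28.6% of its vehicle level after 4OHT. Its level was 644 ± 14.5 CPM (SD, n = 3) in vehicle and 181 ± 11.5 CPM (SD, n = 3) in 4OHT cells. The single libraries stood at 631, 660 and 641 CPM against 177, 172 and 194 CPM, so that all 3 values of one group lay below all 3 of the other. The log2 fold change was -1.81 (SE 0.06, 95% interval -1.94 to -1.68, edgeR adjusted p = 1.6e-13). Reads of the tagged copy can be counted under the same symbol, so the values do not separate it from the endogenous gene. Pou5f1, which encodes the core pluripotency factor OCT4, fell by 0.21 on the log2 scale (SE 0.06, edgeR adjusted p = 0.014), and Sox2, its partner, rose by 0.18 (SE 0.06, edgeR adjusted p = 0.0337). Both shifts were close to the limit of the test. Without vehicle replicate 2 the edgeR adjusted p was 0.0717 for Pou5f1 and 0.2 for Sox2, and for Sox2 it was 0.16 without vehicle replicate 3 and 0.0788 without 4OHT replicate 3. An opposite-strand gene, Gm19553, overlaps 21.4% of the exon bases of Pou5f1, and no use of strand in the counting is given in the sources used here.

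Across all tested genes, 3233 of 14458 (22.4%) differed between 4OHT and vehicle cells, 1719 of them higher in 4OHT and 1514 lower. The count depended on the method, with 977 genes in DESeq2, 2093 with quantile normalization in limma-voom and 4073 with the replicate block. Most differences were small: 490 genes changed at least 2-fold (272 higher, 218 lower) and 79 at least 4-fold. The rises with the largest fold changes under the fixed rule were those of Cubn, Bhmt, Srgn, Gata6, Foxq1, Dppa3, Trim43a and Pdgfra. Cubn, an endocytic receptor of the visceral endoderm, went from 0.547 ± 0.0975 to 20.6 ± 2.04 CPM (log2 fold change 5.24, SE 0.15). Bhmt, a betaine-homocysteine methyltransferase, went from 0.198 ± 0.13 to 4.59 ± 2.42 CPM (log2 fold change 5.08, SE 0.27). Trim43a went from 0.59 ± 0.217 to 7.21 ± 2.05 CPM, but 2 other genes match at least 50% of its transcript at 95% identity or more, so its reads can belong to them. The falls with the largest fold changes were those of Vstm5, Fat2, Pla2g4e, Soga3, Pax8, She, Ndufa4l2 and Notch4. Fat2, an atypical cadherin, went from 7.6 ± 0.524 to 0.85 ± 0.748 CPM (log2 fold change -2.56, SE 0.16). Notch4, a Notch receptor, went from 18.4 ± 1.43 to 5.03 ± 0.615 CPM (log2 fold change -1.98, SE 0.11). She, an SH2 domain protein, went from 36.3 ± 1.74 to 7.73 ± 1.77 CPM (log2 fold change -2.07, SE 0.09). All 16 of these genes passed edgeR's test, with the highest adjusted p, 1.03e-06, for Ndufa4l2. Vstm5, Fat2, Pla2g4e, Pax8 and Ndufa4l2 had no read in 4OHT replicate 2, and Bhmt, Srgn and Pdgfra had 1 read there. With 1 read worth 1.91 CPM, that library says little about these genes, so their 4OHT values rest mainly on replicates 1 and 3. Without it Ndufa4l2 again had the highest edgeR adjusted p of the 16, 0.000167.

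**Figure D1:**
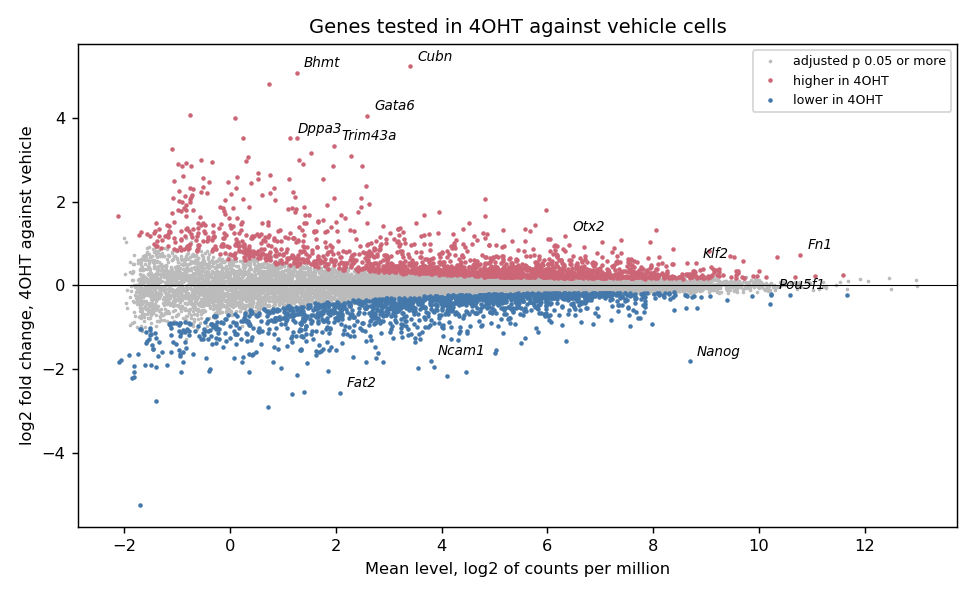
Log2 fold change of each tested gene in 4OHT against vehicle cells (vertical axis) against its mean level over both groups, as log2 of CPM (horizontal axis). Each point is a gene, coloured where its edgeR adjusted p was under 0.05; Nanog lies at -1.81, and Cubn, at 5.24, lies above all other genes.

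The genes around Nanog on its chromosome did not move as a group. Of 12 tested neighbours, Dppa3 and Phc1 rose, A2m fell and 9 did not pass the test. The counts were 2 higher and 1 lower adjusted over the list alone as well. Dppa3, a maternal factor also known as Stella and the nearest tested gene on one side of Nanog, rose 11.4-fold from 0.369 ± 0.0793 to 4.03 ± 0.413 CPM (log2 fold change 3.51, SE 0.22, edgeR adjusted p = 4.74e-10). One other gene matches the Dppa3 transcript over at least 50% of its length at 95% identity or more, so a part of these reads can belong to that copy. Phc1, a Polycomb protein gene, rose from 392 ± 5.51 to 491 ± 3.96 CPM (log2 fold change 0.32, edgeR adjusted p = 0.000216), and A2m fell from 58.1 ± 9.24 to 36.4 ± 5.88 CPM (log2 fold change -0.6, edgeR adjusted p = 0.000283). Gdf3, a TGF-beta family ligand, stood at 111 ± 8.17 and 113 ± 7.66 CPM, with a log2 fold change of 0.05 (95% interval -0.1 to 0.19). Slc2a3, a glucose transporter gene next to Nanog on the other side, stood at 1230 ± 70.6 and 1130 ± 75.1 CPM (log2 fold change -0.12, edgeR adjusted p = 0.198). With the replicate number as a block the adjusted p of Slc2a3 was 0.0261, and without 4OHT replicate 3 it was 0.0353. Apobec1, Mfap5, Foxj2, Necap1, Rimklb and M6pr had log2 fold changes between -0.15 for Mfap5 and 0.09 for Foxj2. The list as a whole had a median log2 fold change of -0.08 but a mean of 0.21 and an upward direction in camera, which Dppa3 sets (camera adjusted p = 0.808).

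**Figure D2:**
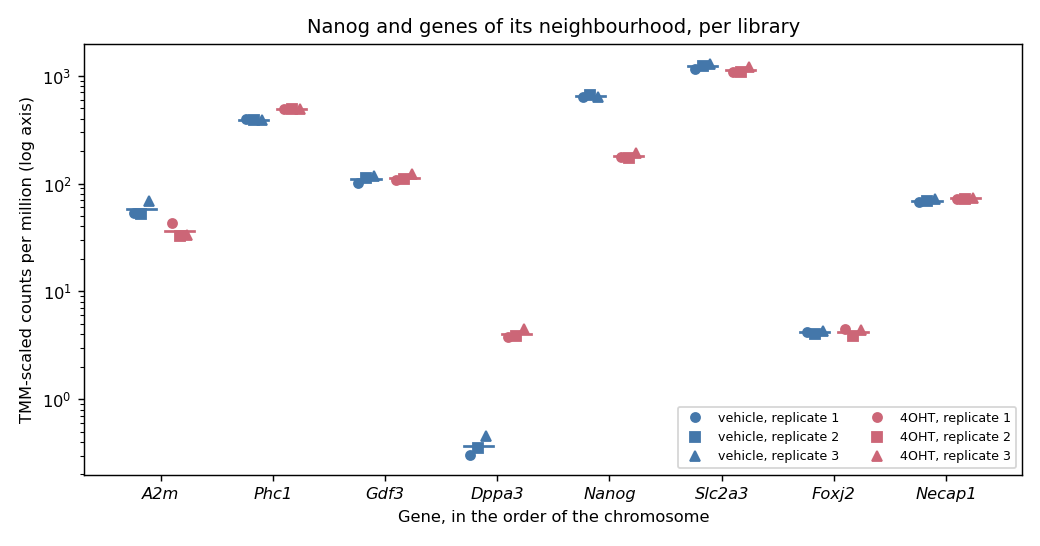
TMM-scaled CPM (log axis) of Nanog and 7 tested genes of its neighbourhood, in chromosome order. Points are single libraries (3 vehicle, 3 4OHT; the symbol gives the replicate) and bars are group means; Nanog lies at 631 to 660 CPM in vehicle and at 172 to 194 CPM in 4OHT libraries, and Dppa3 rises from 0.369 to 4.03 CPM on average.

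The naive pluripotency genes went both ways by small amounts. Of 24 tested members 7 rose, 4 fell and 13 did not pass (9 and 5 adjusted over the list alone), with a median log2 fold change of 0.02 (camera adjusted p = 0.33). Sall4, a zinc finger factor, rose from 324 ± 7.89 to 470 ± 7.87 CPM (log2 fold change 0.54), Klf2 from 363 ± 3.58 to 532 ± 58.2 CPM (0.53) and Fbxo15 from 212 ± 7.41 to 284 ± 3.3 CPM (0.43), each with an edgeR adjusted p of at most 1.13e-05. Fgf4, which encodes the growth factor made by naive cells, fell from 227 ± 3.02 to 182 ± 9.31 CPM (log2 fold change -0.3, edgeR adjusted p = 0.000722). Of the list's other members, Esrrb, Zfp42 and Klf4, picked after their values were seen, did not pass (log2 fold changes 0.03, -0.02 and 0.02). In the formative and primed list, genes of the step that follows naive pluripotency, 7 of 18 tested members rose and 4 fell (8 and 4 adjusted over the list alone; median log2 fold change 0.17, camera adjusted p = 0.178, and 0.0117 with DESeq2). Otx2, a homeobox factor of that step, rose 2.25-fold from 51.5 ± 1.76 to 110 ± 13.5 CPM (SE 0.07 on the log2 scale, edgeR adjusted p = 9.98e-11). The de novo DNA methyltransferase genes Dnmt3a and Dnmt3b rose from 207 ± 5.63 to 293 ± 14.9 and from 209 ± 2.84 to 280 ± 13.7 CPM (log2 fold changes 0.48 and 0.41). Cldn6, a tight junction gene, fell from 18.1 ± 0.768 to 10.9 ± 2.17 CPM (log2 fold change -0.9).

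Genes of the primitive and visceral endoderm, the extraembryonic lineage that lies next to the epiblast, rose together. Of 22 tested members 20 rose, none fell and 2 did not pass (20 and 0 adjusted over the list alone), with a median log2 fold change of 1.07. No member was lower at an unadjusted p under 0.05 in edgeR, and DESeq2 called 15 higher and 0 lower. The transcription factor gene Gata6 rose 16.6-fold from 0.711 ± 0.148 to 11.3 ± 0.875 CPM (edgeR adjusted p = 1.44e-12). Pdgfra, a receptor of primitive endoderm cells, rose from 0.711 ± 0.359 to 5.04 ± 2.84 CPM (log2 fold change 3.17). Dab2, an endocytic adaptor, rose from 2.21 ± 0.211 to 9.66 ± 3.47 CPM (2.38), and Srgn, a proteoglycan gene, from 0.122 ± 0.0266 to 3.2 ± 1.24 CPM (4.8). Among members picked after their values were seen, the factor genes Gata4 and Sox17 rose with log2 fold changes of 2.53 and 3.53. Their 4OHT levels were 5.32 ± 4.63 and 2.08 ± 1.87 CPM, and neither had a read in the shallow 4OHT replicate 2. Lamc1, a basement membrane laminin gene also picked in this way, rose from 666 to 1000 CPM (0.59). Amn and Sparc did not pass (log2 fold changes 0.27 and -0.03). Many members remained low, since Gata6 in 4OHT cells stood at 11.3 CPM beside 1120 CPM for Pou5f1. Foxq1, with a log2 fold change of 3.51, shares 66.1% of its exon bases with the opposite-strand gene A530084C06Rik, so its value is uncertain. The list passed the camera test (adjusted p = 9.58e-25 with a preset correlation of 0.01), and the adjusted p was 0.46 with an estimated correlation, whose unadjusted p was 0.0192. Without the shallow 4OHT replicate 2 the counts were again 20 and 0.

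**Figure D3:**
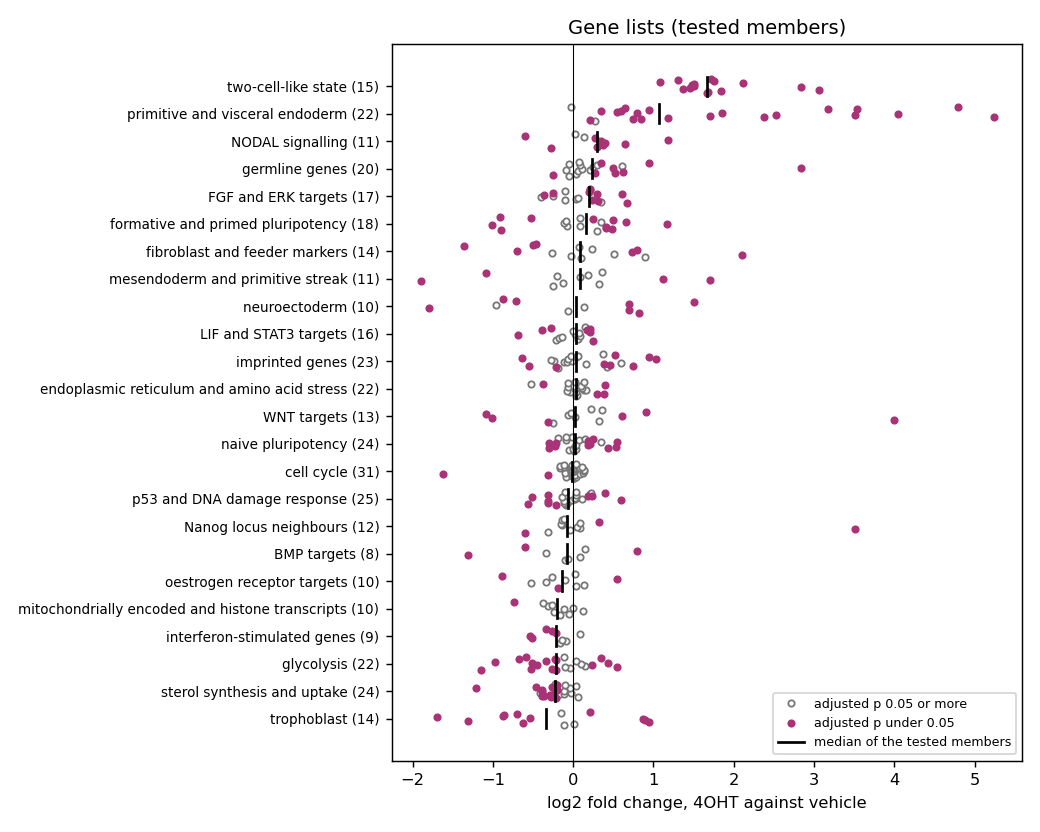
Log2 fold changes in 4OHT against vehicle cells (horizontal axis) of the tested members of the 24 gene lists (vertical axis, ordered by median, with the number of tested members in brackets). Points are genes, filled where the edgeR adjusted p was under 0.05, and the bars are list medians; the two-cell-like list has the highest median, 1.67, and the trophoblast list the lowest, -0.34.

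All 15 tested members of the two-cell-like list rose (15 adjusted over the list alone), genes that mark a rare state of stem cell cultures resembling the embryo after its first division. The median log2 fold change was 1.67 (camera adjusted p = 1.4e-15, and adjusted p = 0.519 with an estimated correlation). Pramel7 rose from 0.333 ± 0.174 to 2.21 ± 0.288 CPM (log2 fold change 3.06, SE 0.3), Usp17le from 1.54 ± 0.135 to 4.8 ± 0.821 CPM (1.51) and Gm8300 from 2.09 ± 0.135 to 6.43 ± 0.667 CPM (1.68). Zscan4c rose from 1.05 ± 0.214 to 3.65 ± 0.368 CPM (1.76), a value that is uncertain because 8 other genes match its transcript at 95% identity or more. All these levels were low, and DESeq2 called 6 of the 15 with all libraries in the fit. Without 4OHT replicate 2 edgeR again called 15. In the germline list 7 of 20 tested members rose and 1 fell (7 and 1 adjusted over the list alone; median log2 fold change 0.23, camera adjusted p = 0.0298, and adjusted p = 0.519 with an estimated correlation). Stra8, a gene of the entry into meiosis, rose from 1.51 ± 0.253 to 9.74 ± 2.29 CPM (log2 fold change 2.84, SE 0.16, edgeR adjusted p = 6.72e-11), while the piRNA pathway gene Stk31 went from 7.97 ± 0.585 to 14.3 ± 5.89 CPM (0.49, edgeR adjusted p = 0.00401). The camera adjusted p of the germline list was 0.0742 without vehicle replicate 1, 0.107 without 4OHT replicate 1, 0.0802 with DESeq2 and 0.0536 with a mean count of at least 50. Without 4OHT replicate 2, 5 of its members rose and 1 fell.

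Lists of other lineages gave mixed directions. Among 14 tested trophoblast genes 7 fell and 4 rose (7 and 4 adjusted over the list alone; median log2 fold change -0.34, camera adjusted p = 0.0436, and adjusted p = 0.519 with an estimated correlation). The epithelial keratin genes Krt19 and Krt8 fell from 7.31 ± 1.38 to 2.74 ± 0.943 and from 12 ± 0.674 to 8.15 ± 2.9 CPM (log2 fold changes -1.7 and -0.86), and the transcription factor genes Tead4 and Ets2 fell with log2 fold changes of -0.7 and -0.62. With the replicate number as a block the camera adjusted p of the trophoblast list was 0.193. It was 0.0525, 0.0559, 0.196 and 0.198 without vehicle replicates 2 and 3 and 4OHT replicates 1 and 3, and 0.0616 with DESeq2, 0.107 with quantile normalization and 0.0851 with no filter on low counts. Of 10 tested neuroectoderm genes 4 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.774), with a median of 0.04 but a mean of -0.06 and a downward direction in camera. Ncam1, a neural adhesion molecule, fell from 22.7 ± 0.475 to 5.02 ± 2.69 CPM (log2 fold change -1.8, edgeR adjusted p = 6.72e-11), and Tubb3, a neuronal tubulin, from 113 ± 3.92 to 71.8 ± 5.81 CPM (-0.71). Sox21 rose from 5.55 ± 0.0715 to 17.4 ± 3.19 CPM (log2 fold change 1.5). In the mesendoderm and primitive streak list 2 of 11 tested members rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.774). Evx1 fell (log2 fold change -1.9) and Foxa2 and Gsc rose (1.71 and 1.12), from vehicle levels of 0.75, 0.189 and 0.84 CPM. With quantile normalization in limma-voom the adjusted p of these genes were 0.0717, 0.0963 and 0.0655, and DESeq2 with all libraries called no member of the list.

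Among signalling lists, NODAL pathway genes rose in part: 7 of 11 tested members rose and 2 fell (7 and 2 adjusted over the list alone; median log2 fold change 0.29). Nodal rose from 83.6 ± 1.13 to 109 ± 5.65 CPM (log2 fold change 0.34, edgeR adjusted p = 0.000214). Lefty1, its target and antagonist, rose from 27.9 ± 3.78 to 43.7 ± 2.43 CPM (0.64, edgeR adjusted p = 1.45e-05). The inhibitory SMAD gene Smad7 fell from 193 ± 12.4 to 130 ± 9.83 CPM (-0.6, edgeR adjusted p = 1.7e-06). The camera adjusted p of this list was 0.0773, and it was 0.0415 with the replicate number as a block, 0.0473 without vehicle replicate 3, 0.0457 with no filter on low counts and 0.0488 with quantile normalization. For FGF and ERK targets 8 of 17 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.178), Dusp4 and Myc with log2 fold changes of 0.67 and 0.3 and Il17rd, an antagonist, with -0.37. For WNT targets 3 of 13 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.382). The WNT antagonist gene Dkk1 rose 16-fold (log2 fold change 4, edgeR adjusted p = 5.22e-06; 3.98 and 0.000311 without 4OHT replicate 2) from a mean of 0.0544 ± 0.0568 CPM to 0.859, 3.82 and 1.6 CPM in 4OHT replicates 1 to 3. Tnfrsf19 rose from 16 ± 0.428 to 27.7 ± 4.18 CPM, and Sp5 fell (log2 fold change -1.09, edgeR adjusted p = 0.00506, and 0.11 without 4OHT replicate 1). LIF and STAT3 targets gave 4 rises and 3 falls among 16 (5 and 4 adjusted over the list alone; camera adjusted p = 0.762), with a median of 0.04 against a mean of -0.04 and a downward direction in camera; with the replicate number as a block 5 rose and 5 fell. Junb fell from 43 ± 0.325 to 29.2 ± 4.69 CPM. Of 8 tested BMP targets Msx2 rose and Smad7 and Gata2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.413), and the edgeR adjusted p of Msx2 was 0.0745 without 4OHT replicate 3. DESeq2 with all libraries called 2 rises and 1 fall for NODAL, 0 and 2 for FGF and ERK, 3 and 1 for WNT, 0 and 3 for LIF and STAT3 and 0 and 1 for BMP. The BMP targets Id1 to Id4 were not analysed here.

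The glycolysis, sterol and interferon-stimulated lists each had more falls than rises in edgeR. Of 22 tested glycolysis genes 12 fell and 4 rose (12 and 5 adjusted over the list alone; median log2 fold change -0.22, camera adjusted p = 0.00976, and adjusted p = 0.551 with an estimated correlation). Pfkp, the platelet-type phosphofructokinase gene, fell from 251 ± 21 to 126 ± 10.5 CPM (log2 fold change -0.97, SE 0.07, edgeR adjusted p = 7.2e-09), Aldoc from 16.1 ± 1.57 to 5.46 ± 3.11 CPM (-1.15) and Tpi1 from 402 ± 42.7 to 269 ± 3.85 CPM (-0.59). Hk1, a hexokinase gene, rose from 130 ± 3.49 to 190 ± 5.05 CPM (0.54). In the sterol list 13 of 24 tested genes fell and none rose (15 and 0 adjusted over the list alone; median log2 fold change -0.23, camera adjusted p = 8.19e-05, and adjusted p = 0.519 with an estimated correlation). The cholesterol synthesis genes Pmvk, Dhcr7 and Msmo1 fell with log2 fold changes of -0.47, -0.39 and -0.39, and Insig1, a sterol sensor, with -0.39; each had an edgeR adjusted p of at most 0.000848. At an unadjusted p under 0.05 edgeR had 15 sterol genes lower and 0 higher, and DESeq2 with all libraries called 4 lower and 0 higher. Of 9 tested interferon-stimulated genes 5 fell and none rose (5 adjusted over the list alone; median log2 fold change -0.22, camera adjusted p = 0.0114, and adjusted p = 0.519 with an estimated correlation), among them Irf9 from 13.6 ± 0.111 to 8.28 ± 2.27 CPM (-0.51) and Oas1a (-0.54), which has a near-identical copy. The camera adjusted p of this list was 0.181 without 4OHT replicate 2 and 0.122, 0.169 and 0.141 without vehicle replicates 1, 2 and 3, 0.062 with DESeq2 and 0.509 with no filter on low counts, and DESeq2 called 0 of its members, with 3 lower at an unadjusted p under 0.05. In edgeR no member was higher at that unadjusted p.

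Most cell cycle genes did not pass the test. Of 31 tested members 2 fell and none rose (2 and 0 adjusted over the list alone; camera adjusted p = 0.382). Ccnd2, a cyclin of the G1 phase, fell from 48.3 ± 4.17 to 16.2 ± 0.886 CPM (log2 fold change -1.62, SE 0.08, edgeR adjusted p = 2.94e-11), and Ccnd1, which overlaps an opposite-strand gene over 21.9% of its exon bases, from 243 ± 2.82 to 194 ± 2.87 CPM (-0.32). At an unadjusted p under 0.05 edgeR had 4 members lower and 0 higher, and DESeq2 called 2 lower and 0 higher. Pcna, which has a near-identical copy, and Mcm5 had log2 fold changes of -0.16 each (edgeR adjusted p = 0.0533 and 0.0653). With the replicate number as a block their adjusted p were 0.00803 and 0.00462, and 6 members fell and 1 rose. The p53 and DNA damage list gave 4 rises and 6 falls among 25 tested genes (5 and 6 adjusted over the list alone; camera adjusted p = 0.577), with Ei24 at 0.6 and the antiproliferative gene Btg2 at -0.56 on the log2 scale. The endoplasmic reticulum and amino acid stress list gave 3 rises and 1 fall among 22 (3 and 1 adjusted over the list alone; camera adjusted p = 0.382), with Atf4 from 105 ± 2.02 to 139 ± 11.3 CPM. Whether the listed oestrogen receptor targets respond to 4OHT in these cells was not tested. Of 10 tested members Nrip1 rose (0.54) and Cited2 and Pgr fell (-0.19 and -0.89). The counts were 1 and 2 adjusted over the list alone as well, and the camera adjusted p was 0.577. Cited2 and Pgr lost their calls without 4OHT replicate 1 (edgeR adjusted p = 0.243 and 0.216), and also without each of vehicle replicates 1 and 2 (0.098 and 0.0868 for Cited2, 0.414 and 0.0598 for Pgr). Cited2 lost it too without vehicle replicate 3 (0.0941) and Pgr without 4OHT replicate 2 (0.0733).

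Imprinted genes gave 6 rises and 3 falls among 23 tested members (9 and 3 adjusted over the list alone; camera adjusted p = 0.212). Peg10, a retrotransposon-derived paternally expressed gene, rose from 163 ± 6.83 to 330 ± 10.1 CPM (log2 fold change 1.03, SE 0.06, edgeR adjusted p = 1.08e-10), Igf2r rose from 99.9 ± 3.32 to 136 ± 5.48 CPM (0.46), and Phlda2 fell from 49 ± 1.74 to 33.1 ± 4.15 CPM (-0.64). Markers of fibroblasts and feeder cells, which stem cell cultures can hold, gave 3 rises and 4 falls among 14 (5 and 5 adjusted over the list alone; camera adjusted p = 0.976), with an upward direction in camera and a downward one in fry. Fn1, the fibronectin gene, rose from 1320 ± 49.4 to 2200 ± 36.4 CPM (log2 fold change 0.73, edgeR adjusted p = 1.08e-08). Col5a2, a fibrillar collagen gene, rose from 0.718 ± 0.194 to 3.99 ± 1.51 CPM (2.1, edgeR adjusted p = 2.71e-07), and Loxl1, picked after its values were seen, from 2.79 ± 0.353 to 4.48 ± 0.581 CPM (0.8, edgeR adjusted p = 0.000294). Thy1, a surface glycoprotein gene, fell from 15.9 ± 0.52 to 6.67 ± 0.874 CPM (-1.36, edgeR adjusted p = 3.57e-09). The summed level of the collagen genes Col1a1, Col1a2 and Col3a1 was 1.99 ± 0.092 CPM in vehicle and 2.24 ± 0.397 CPM in 4OHT cells. Of 10 tested histone genes Hist2h3c1 alone passed, lower, in the test over all genes (none adjusted over the list alone; camera adjusted p = 0.233), and it lost this call with the replicate block (0.0626) and in each fit that left out 1 library but that without 4OHT replicate 3. Its reads are shared with Gm20634, which covers 100% of its exon bases. Mitochondrially encoded transcripts were not analysed here.

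The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. All 4OHT samples carried the floxed element, so the effect of 4OHT itself could not be separated from that of the element.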

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

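The fall of Nanog kept its direction and its call in all alternatives, with log2 fold changes from -1.87 to -1.75 when single libraries were left out and -1.83 to -1.76 otherwise. The number of changed genes moved more. It was 2093 (1125 higher, 968 lower) with quantile normalization in limma-voom, 977 (568 higher, 409 lower) with DESeq2 and 490 (272 higher, 218 lower) with an added log2 fold change of at least 1. With all libraries thinned to the shallowest it was 110 (68 higher, 42 lower), and 4 lists passed; the lower depth of that alternative is its construction. With estimated correlations 0 lists passed camera. For DESeq2, the median dispersion was 0.0165 with all libraries and 0.0054 without 4OHT replicate 2, where it called 2422 genes. The median gene-wise dispersions that edgeR estimated were 0.00359 and 0.00352. Its quasi-likelihood test uses another measure of spread, the quasi-dispersion, so these medians are not a like comparison of the methods. The cause was not tested for quantile normalization. With the replicate block 4073 genes were called (2115 higher, 1958 lower), 3158 of them among the 3233. Beyond the list and gene calls given with the results, the block moved Igfbp4 and H1f0 past the threshold (adjusted p = 0.0191 and 0.0151) and changed no other call of a list or named gene. Leaving out single libraries gave 2368 to 3950 changed genes, 1218 to 1950 higher, 1150 to 2019 lower, and 5 to 6 lists. Without 4OHT replicate 2 the count was 3140. Under thinning 4 named genes took the opposite sign, or none at 2 decimals, without passing; the reads left are few: Cited2 0.25, Notum -0.13, Oas1a 0.32 and Pgr 0. Over all settings, named genes lost a call with the same direction in 218 comparisons, beside these 4, and gained one in 20, and lists lost one in 31 and gained one in 6. DESeq2 gave no adjusted p for 6 named genes, not counted above, among them Evx1, Hist2h3c1, Pgr and Sp5, and did not call Sox2, Insig1, Irf9, Oas1a, Stk31, Foxa2, Gsc, Dusp4, Myc, Nrip1, Cited2, Msx2 and Gata2. The pseudocount alternative applied only to the prior count of the fold changes. The depth of 4OHT replicate 2, 515388 counts, limits what that library shows to genes of several CPM.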

Other observations

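Families of genes that share a symbol stem were searched beyond the fixed lists. Of 220 families with at least 8 tested members, 4 passed camera with the preset correlation and kept their direction without 4OHT replicate 2, and none passed with an estimated correlation (adjusted p = 0.988 for these 4, with 2 of the 220 families at an unadjusted p under 0.05). Claudins, which build tight junctions, were lower in 4OHT: 5 of 9 tested members fell and none rose (median log2 fold change -0.9, camera adjusted p = 0.0123). Cldn4 fell from 78.1 ± 3.42 to 35.5 ± 2.69 CPM, and Cldn3 and Cldn7 had log2 fold changes of -1.85 and -1.16. Keratins, the intermediate filaments of epithelia, were lower too, with 6 of 10 falling and none rising (median -0.61, camera adjusted p = 0.0123). Among them were Krt42 and Krt17 (log2 fold changes -0.68 and -0.71). The other falling keratins, Krt7, Krt18, Krt8 and Krt19 (-0.88, -0.54, -0.86 and -1.7), are members of the trophoblast list. The falls of the keratin family and of that list are thus in part the same genes. The DOCK exchange factors of small GTPases were higher, with 5 of 11 rising and none falling (median 0.26, camera adjusted p = 0.0372); Dock6 rose from 121 to 197 CPM. All 12 tested gamma-protocadherins of the A group fell by similar amounts (median -0.21, camera adjusted p = 0.0146). Their vehicle levels lay between 72.4 and 77.6 CPM, and their levels in 4OHT replicate 1 between 61.8 and 66.7 CPM. These genes share constant exons, and reads there can be counted for each of them. They were therefore taken as a single signal. The camera p, which treats them as 12 nearly independent genes, carries no weight for this family. Apart from Krt8 and Krt19, the genes named in this paragraph were picked after their values were seen.

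For what follows, the tests of other splits, of 4OHT acting alone, of feeder cells and of a share of endoderm cells were chosen after the results were seen, and the others before. The 3233 changed genes were weighed first. The real split of the 6 samples gave 3233 genes, and the highest of the other 9 splits gave 0 in edgeR. These had from 9 to 854 genes at an unadjusted edgeR p under 0.05. Each of them mixes vehicle and 4OHT samples within its groups, so a real difference would widen the spread there. Their low counts therefore cannot show that the real split stands out. With 10 splits in all, 1 of which gave as many genes, a share under 0.05 cannot be reached. Only 4 splits, the real one included, part all 3 same-numbered pairs. With the replicate block the real one gave 4073 genes and the others 751, 0 and 0 (2768, 4 and 11 at an unadjusted p under 0.05). The 751 came from the split that exchanges the samples of replicate 2, the pair with the shallow library. That split keeps the real groups for replicates 1 and 3. The technical explanations tested were the shallow library and a bias by GC content or transcript length. Without the shallow 4OHT replicate 2, edgeR called 91.7% of the genes again in the same direction, which argues against that library as their source. The edgeR model weighs libraries by depth, so that library had little part in its calls. DESeq2 called 977 genes with it and 2422 without it. In the blocked fit GC content and transcript length accounted for an R2 of 0.008 of the fold changes of called genes. This argues against such a bias (95.4% of the genes had a value). A difference in handling between the groups was not tested. An effect of 4OHT apart from the floxed element cannot be told apart from one of the element, since all 4OHT samples carried it; the oestrogen receptor list had a camera adjusted p of 0.577, which does not exclude such an effect. The biological explanation the design names, the loss of the element with the fall of Nanog, stays open in the same way.

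The rise of the primitive and visceral endoderm list was weighed next. Carried-over feeder fibroblasts were argued against only as far as the collagen genes Col1a1, Col1a2 and Col3a1 stand for them. Their sum, low in both groups (1.99 and 2.24 CPM), differed by 0.242 CPM, within its spread. The summed endoderm list rose by 612 CPM from 1620 ± 24.1 to 2230 ± 23.2 CPM, with Lamc1 alone going from 666 to 1000 CPM. Other members of the fibroblast list did rise, among them Fn1 from 1320 ± 49.4 to 2200 ± 36.4 CPM (log2 fold change 0.73). Col5a2 and Loxl1 rose too (2.1 and 0.8), while Thy1 and Fstl1 fell (-1.36 and -0.7). The list as a whole went both ways and does not settle the point. A bias by GC content or length was argued against as well, since the median log2 fold change of the list in the blocked fit was 1.06 before and 1.02 after the trend was removed. It stays open whether a small share of cells had turned into endoderm or whether many cells raised these genes a little, because a profile of pure endoderm cells was not analysed here; 0 of the 22 tested members fell, which fits both.

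The rise of the two-cell-like list was weighed last. All 6 of the 6 tested members without a counted near-identical copy rose, among them Pramel7, Gm8300 and Usp17le. The count depends on the length of each member's own transcript. Usp17la, Usp17le and Tcstv3 had no counted copy, while the like-named Usp17lc and Tcstv1 had 1 each. Members without a counted copy may therefore still share reads with related genes. The rises argue against shared reads as the only source just as far as this count finds all copies. The shallow library is no sufficient explanation: 15 of 15 members were called higher with and without 4OHT replicate 2. The list was low in both groups, and whether a larger share of cells in this state or a higher level per cell lies behind the rise was not tested.

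Further hypotheses were tested with these results. If the changes spread from the floxed element to neighbouring genes, called genes should be more frequent near Nanog: 3 of the 20 nearest tested genes were called (15%, exact 95% interval 3.21% to 37.9%) against 22.4% of the others (two-sided Fisher's exact p = 0.594), an interval too wide to exclude either direction. A chromosome gained or lost in part of one group's cells should shift that chromosome's genes, but the largest distance of a chromosome's median log2 fold change from that of all genes was 0.033. The search for gene families gave 4 families with camera's preset correlation: claudins, keratins, DOCK factors and protocadherins. None of them passed camera with an estimated correlation (adjusted p = 0.988 for each). The protocadherins were taken as a single signal, so their camera p carries no weight.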
